A study of Mus musculus with 8 samples.

How the data were processed

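RNA was measured in the vagal region, the part of the embryo beside somites 1 to 7, of mouse embryos at embryonic day 9.5. Per the labels, 4 samples came from Rdh10 trex/trex mutants (called trex here) and 4 from wild type embryos (wt), and poly-A selected, strand-specific libraries were made from total RNA. Replicates are numbered 1 to 4 in each group by the replicate label; the titles and table columns number the wt samples 5 to 8 instead, in the same order. The labels do not say whether a sample is 1 embryo or a pool, nor whether samples of a group came from separate litters, so p-values measure the spread between these samples, which may be partly technical.

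The deposited values are TPM, transcript abundances scaled by gene length and library total, 1 column per sample, each summing to 1000000. Per the submitters' processing notes, CASAVA 1.8.2, STAR and the mm10 build were used. The read counter, its strand setting, the treatment of reads that map to several places, the annotation release and the gene lengths behind the TPM values are not given in the sources used here. Gene symbols, coordinates and lengths were taken from GENCODE M21, which is on the same assembly as mm10. Of the 55421 gene identifiers in the table, 55240 matched.

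TPM keeps no depth, so depth was sought in the low values. Multiplied by a gene's exonic length, between 98.7% and 98.9% of the low values of a sample (up to 200 reads) were a whole multiple of 1 step within 0.001 read. The whole reads recovered this way came to between 20928971 and 23648645 per sample. At this depth 15717 genes had a mean TPM of at least 1 over the 8 samples and were tested. These recovered reads served only to state depth, to compare libraries and for an added alternative, since the deposited unit is TPM.

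The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(TPM + 1), two-sided, with genotype as the only term and Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p below 0.05. Every adjusted p of a gene is from this test unless an alternative is named with it. Log2 differences are on the log2(TPM + 1) scale, which understates the change of weakly expressed genes. Folds are ratios of group mean TPM. Values are means ± SD over the 4 samples of a group. The step was tested on simulated data of 15717 genes for this comparison with 50 changed genes of each size and a list of 20 further genes raised by 0.5. It recovered 46% of genes changed by 0.5 on the log2 scale, 86% at 1, 92% at 1.5 and 98% at 2, and its 185 calls were 161 changed genes, 15 genes of the list and 9 unchanged genes. The simulated noise was independent between genes, and the changed genes were taken from those with a mean log2(TPM + 1) above 2. Genes of the real libraries vary together, so these rates need not hold there.

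Before the data were examined, 40 gene lists were fixed from textbook markers of this region, of retinoic acid signalling and of other cell types that a dissection could hold. They were tested with camera from limma (preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 40 lists), which asks whether list members move further in a direction than other genes. Its variance trend was left open beforehand and was set to match the gene test; without it the same 12 lists passed. Camera with an estimated correlation and fry were run beside it. Where a list is reported, its members are counted as called over all genes tested and as adjusted over the list alone.

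Genes were named by a rule fixed at the same time, which took 71 genes. It took Rdh10; the 8 largest rises and 8 largest falls among called genes whose 4 trex and 4 wt values did not overlap, leaving out predicted and unnamed genes, pseudogenes, globins and sex chromosome markers; the 3 called members with the smallest p from each of 12 lists closest to the study's question and 1 from each of the others; and, whatever their test result, a fixed set of genes that included Ret, Sox10, Ednrb, Gfra1, Gdnf, Aldh1a2, Rarb, Cyp26a1, Crabp2, Hoxb1, Tbx5 and Nkx2-5. Some genes that the rule took are not reported here by name or drawn as single genes, but they remain in the counts. Any other gene named below was chosen after its values were seen.

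Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter at a mean TPM of 5, median-of-ratios rescaling, quantile normalization, TPM recomputed without globin, mitochondrial and sex chromosome genes, eBayes without a trend or with robust estimation, array weights, the replicate number as a block, leaving out each sample, and leaving out genes on chromosome 1 within 20 Mb of Rdh10. Alternatives added after seeing the data were limma voom on the recovered reads, sex as a covariate, read from Y-linked genes (a summed TPM of Ddx3y, Eif2s3y, Kdm5d and Uty above 1), the 6 samples below that level alone, each pair of wt samples left out, the mean level of the liver list as a covariate, and camera without a variance trend.

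Several properties of the values limit single genes. The genes mt-Co2, mt-Co3 and mt-Atp6 are listed at 0 in every sample and were not tested. Hk3 and Unc5a overlap at their ends in the annotation, Hoxc6 and Hoxc8 overlap annotated Hoxc5 transcripts, Hoxa4 overlaps those of Hoxa3 and Gm28308, Foxc2 overlaps Gm20388, Lef1 overlaps Gm42449, Mir7059 overlaps Cln3, and Hoxb5, among others, overlaps an antisense gene, so reads could be shared there. Ldha and Krt8 have annotated pseudogene copies. Aldoa stands under 2 gene identifiers and counts as 2 members of its list.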

Results

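The data were 8 RNA-seq libraries of the vagal region of mouse embryos at embryonic day 9.5, the level of somites 1 to 7 from which most enteric neural crest cells leave the neural tube. Of these, 4 libraries came from embryos homozygous for the trex allele of Rdh10 and 4 from wt embryos. Rdh10 encodes the retinol dehydrogenase that makes retinaldehyde, the precursor of retinoic acid. The series asks how gene expression in this region differs between the genotypes. Recovered depth ranged from 20928971 reads in trex replicate 3 to 23648645 reads in trex replicate 1. Correlations of log2(TPM + 1) between libraries ran from 0.979 to 0.987 within wt, from 0.964 to 0.988 within trex and from 0.944 to 0.981 between the groups. No pair of libraries agreed within sampling noise, the smallest chi-square per gene being 5.14. The first principal component held 43.1% of the variance and separated the genotypes, but the trex libraries spread far more widely along it than wt. Trex replicate 1 lay farthest out at -56.8 and trex replicate 2 nearest to wt at -2.05, with wt between 21.3 and 28.0. The chi-square per gene of trex replicate 2 was 17.3 to 24.2 against the wt libraries. Against trex replicates 3, 4 and 1 it was 16.6, 29.5 and 71.9. By this measure trex replicate 2 was closer to every wt library than to trex replicates 1 and 4.

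Rdh10 transcripts were more abundant in the mutants. The gene (ENSMUSG00000025921, chromosome 1, 16105774 to 16133734, mm10) stood at 76.0 ± 20.2 TPM in trex and 38.8 ± 2.20 TPM in wt (SD, n = 4 each), a 1.96-fold difference. The 4 trex libraries held 106, 66.2, 62.7 and 69.0 TPM, and the highest wt library held 41.0 TPM. The log2 difference was 0.92 ± 0.15 (SE) with an adjusted p of 0.0126 in limma, and an exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows. The adjusted p was 0.054 without wt replicate 2. The trex allele is a mutation that need not lower the transcript, so this level does not check the labels.

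Between the genotypes 1369 of 15717 tested genes differed, 777 higher and 592 lower in trex, and 282 of them differed by at least 1 on the log2 scale. The largest rises under the naming rule were those of Hoxc8, Ier3, Hoxb9, Ddit4, Hoxa7, Hoxc6 and Hand1. Hoxc8 (ENSMUSG00000001657, chromosome 15, 102990607 to 102994111) rose from 0.396 ± 0.383 to 22.6 ± 5.30 TPM, with a log2 difference of 4.09 ± 0.23 and an adjusted p of 0.000169. Hand1, a transcription factor of heart and lateral mesoderm, rose from 9.56 ± 3.71 to 63.3 ± 40.0 TPM. The microRNA gene Mir7059 also met the rule, but it rested on at most 2 reads in any library. The largest falls were those of Myh3, Tnnc2, mt-Tl1, Hk3, Unc5a, Nhlh2, Chrna3 and Barx1. Unc5a, a netrin receptor gene (ENSMUSG00000025876, chromosome 13, 54949411 to 55006018), had the smallest p of all named genes and fell from 39.7 ± 4.25 to 5.35 ± 0.42 TPM, 7.42-fold, with an adjusted p of 9.11e-06. The muscle genes Myh3 (embryonic myosin heavy chain) and Tnnc2 (fast troponin C) fell 8.70-fold and 7.55-fold, Chrna3 (a nicotinic receptor subunit of autonomic neurons) 11.5-fold, and Barx1 (a transcription factor of stomach mesenchyme) 7.87-fold. Leaving out single libraries ended the calls of Ier3 and mt-Tl1 (7 of 8 libraries each, adjusted p up to 0.104 and 0.117) and of Hand1 and Barx1 (6 libraries each, up to 0.104 and 0.109), and leaving out wt replicate 2 that of Tnnc2 (0.0616). The groups did not overlap for 21.8% of tested genes, where chance gives 2.86%.

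The number of genes called depended on single libraries. It was 2926 without trex replicate 2, 592 without trex replicate 3, 375 without trex replicate 4, and 462, 199, 394 and 611 without wt replicates 1, 2, 3 and 4. Y-linked transcripts summed to 162 and 158 TPM in wt replicates 2 and 3 and to at most 0.0662 TPM in the other 6 libraries, and 39 genes were called with sex as a covariate; leaving out any 2 wt libraries gave between 8 and 164. The excess of higher genes depended on the scaling. After quantile normalization 633 genes were higher and 739 lower, and after median-of-ratios rescaling 687 and 695. Recomputing TPM without globin, mitochondrial and sex chromosome genes gave 658 and 704, and voom on the recovered reads 632 and 794.

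**Figure D1:**
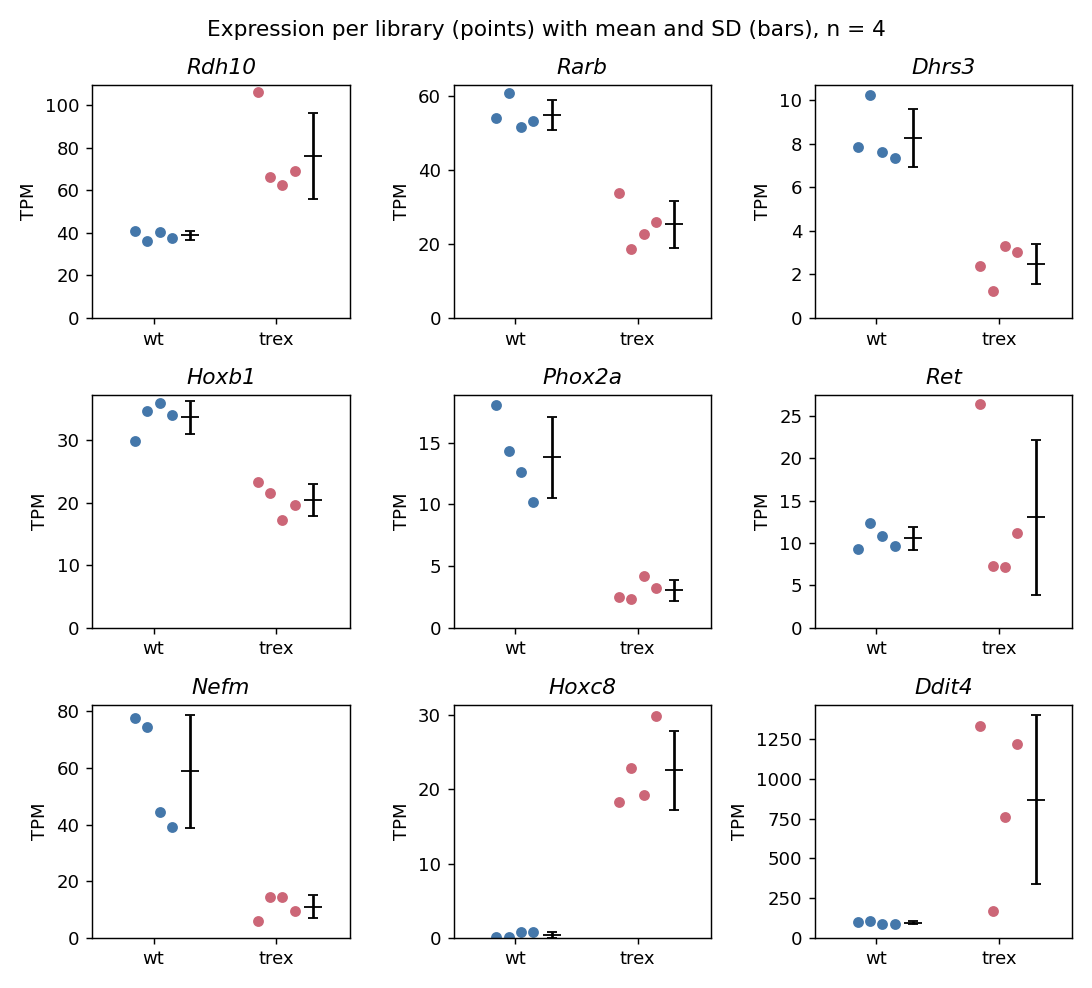
TPM of 9 genes in each of the 4 wt and 4 trex libraries (points), with the group mean and SD (bars); each vertical axis starts at 0. Rdh10, Hoxc8 and Ddit4 lie higher and Rarb, Dhrs3, Hoxb1, Phox2a and Nefm lower in every trex library than in any wt library, while Ret overlaps.

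Genes that respond to retinoic acid were mostly lower in trex. Of 24 measured members of that list 12 fell, 1 rose and 11 were not called; adjusted over the list alone, 14 fell and 2 rose. Rarb, the retinoic acid receptor whose gene is itself induced by retinoic acid, fell from 54.9 ± 4.10 to 25.3 ± 6.40 TPM (2.17-fold, adjusted p = 0.00777). Tshz1 fell from 110.5 ± 8.68 to 51.3 ± 1.15 TPM (2.15-fold, adjusted p = 0.000169), Cdx1 2.31-fold and Crabp2, a carrier that brings retinoic acid to its receptor, 1.498-fold. The list passed camera with an adjusted p of 2.8e-08, and had an adjusted p of 0.29 with an estimated correlation. Among 14 genes of retinoid metabolism 2 rose and 3 fell; adjusted over the list alone, 3 rose and 4 fell. Dhrs3, which reduces retinaldehyde back to retinol, fell 3.33-fold, from 8.27 ± 1.34 to 2.48 ± 0.91 TPM. Aldh1a2, which makes retinoic acid from retinaldehyde, rose from 216.5 ± 41.8 to 318.4 ± 41.0 TPM (adjusted p = 0.0436). Cyp26a1, which degrades retinoic acid, stood at 10.9 ± 5.99 TPM in trex and 14.6 ± 5.11 in wt and was not called (adjusted p = 0.407). Rarb was the single called gene of 12 receptors and co-regulators; adjusted over the list alone, 2 fell and 1 rose. Leaving out single libraries ended the calls of Aldh1a2 (6 of 8 libraries, adjusted p up to 0.131) and Cdx1 (5 libraries, up to 0.0785), and of none of Rarb, Tshz1, Crabp2 and Dhrs3.

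Hox genes, which give the body axis its regional identity, split by their position in the clusters. Of 15 genes of groups 1 to 5, 7 fell, none rose and 8 were not called; adjusted over the list alone, 9 fell and 1 rose. Hoxb1 fell 1.65-fold, Hoxa4 1.92-fold and Hoxb5 1.58-fold, the last from 36.2 ± 3.29 to 22.9 ± 2.40 TPM. Of 13 measured genes of groups 6 to 13, 6 rose and none fell; adjusted over the list alone, 10 rose. Hoxc6 rose from 5.14 ± 3.96 to 31.5 ± 5.48 TPM, Hoxa9 from 0.948 ± 1.01 to 6.65 ± 0.40, Hoxb9 from 59.2 ± 48.0 to 330.8 ± 51.7 and Hoxb7 2.28-fold. The mean log2 level of the list was 1.91, 1.56, 3.46 and 3.24 in wt replicates 1 to 4 and between 3.92 and 4.38 in trex. Liver markers also varied between libraries, with a mean log2 level of 1.16, 1.01, 3.33 and 3.33 in the wt libraries and 1.20, 1.85, 3.69 and 4.53 in the trex libraries. Camera gave an adjusted p of 2.12e-06 for groups 1 to 5 and 2.94e-05 for groups 6 to 13. With an estimated correlation the adjusted p was 0.29 and 0.585. Leaving out single libraries ended the calls of Hoxa7 (7 of 8 libraries, adjusted p up to 0.108) and Hoxb9 (5 libraries, up to 0.0871).

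**Figure D2:**
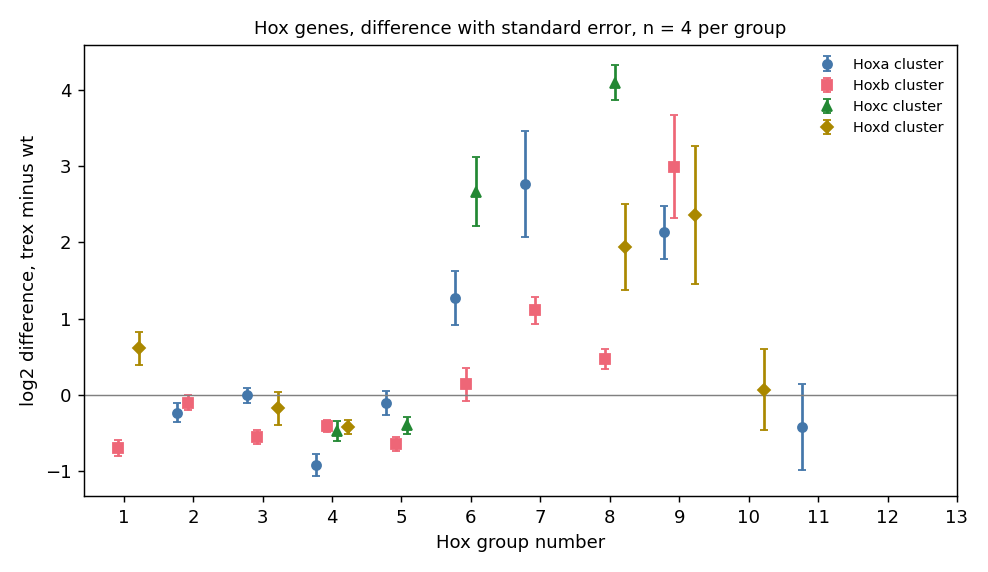
Log2 difference (trex minus wt, of log2(TPM + 1)) with its standard error for 27 of the 28 tested Hox genes, placed by Hox group number and marked by cluster. Genes of groups 1 to 5 lie mostly below 0 and Hoxc8 reaches 4.09.

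Genes of enteric nervous system precursors moved both ways. Of 19 measured members 6 fell and 2 rose; adjusted over the list alone, 7 fell and 4 rose. Phox2a, a transcription factor gene of autonomic and enteric neurons, fell from 13.8 ± 3.30 to 3.05 ± 0.85 TPM (4.53-fold, adjusted p = 0.00333). The GDNF co-receptor gene Gfra1 fell 2.47-fold and the endothelin receptor gene Ednrb 1.599-fold, while Ece1, which activates endothelins, rose 1.54-fold. Ret, the GDNF receptor gene, stood at 13.02 ± 9.09 TPM in trex and 10.6 ± 1.40 in wt (adjusted p = 0.874), with 26.4 TPM in trex replicate 1. Gdnf stood at 3.69 ± 0.47 TPM in trex and 4.26 ± 0.84 in wt (adjusted p = 0.486). Camera did not call this list (adjusted p = 0.0743, and 0.585 with an estimated correlation). It did so as lower without trex replicate 1 (0.0188), without wt replicate 4 (0.0425) and with array weights (0.0281). The list's median log2 difference was 0.015 and its mean was -0.386. Gfra1 was not called without trex replicate 4 or without wt replicate 1 or 2 (adjusted p up to 0.062).

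General neural crest genes were more often higher. Of 22 members 7 rose and 2 fell; adjusted over the list alone, 11 rose and 2 fell. The mesenchymal transcription factor gene Twist1 rose from 255.0 ± 8.98 to 330.3 ± 11.2 TPM, Sox9 1.40-fold and Snai2 1.85-fold (adjusted p = 0.0542 without wt replicate 2). Sox10, a marker of migrating crest, stood at 50.1 ± 11.8 TPM in trex and 35.4 ± 1.25 in wt and was not called (adjusted p = 0.0732). Camera gave an adjusted p of 0.0218, and 0.592 with an estimated correlation. The adjusted p was 0.0883 without trex replicate 2, and 0.108 with array weights.

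Genes of neurons and of neural tube progenitors were lower in trex. Of 18 genes of differentiating neurons 12 fell and none rose; adjusted over the list alone, 14 fell. Nefm, a neurofilament gene, fell from 58.8 ± 19.95 to 10.96 ± 4.10 TPM (5.37-fold, adjusted p = 0.00734), and Nhlh2 fell 7.05-fold (adjusted p = 0.0571 without wt replicate 2). Of 20 genes of neural tube progenitors 7 fell and none rose; adjusted over the list alone, 10 fell. Pax7, of the dorsal neural tube, fell from 12.8 ± 1.63 to 5.04 ± 0.49 TPM, and Neurog1 fell 3.22-fold. Camera gave adjusted p values of 1.16e-11 for neurons and 3.87e-08 for progenitors. With an estimated correlation the adjusted p was 0.29 for each. Hindbrain segmentation genes moved both ways, with 3 of 17 higher and 3 lower; adjusted over the list alone, 6 were higher and 4 lower. Fgf3 rose 3.54-fold, to 25.2 TPM in trex replicate 1 and about 10.3 TPM or less in the others, and was not called without trex replicate 4 or wt replicate 2, 3 or 4 (adjusted p up to 0.0773).

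Mesoderm and endoderm lists held called genes in different proportions. Among 17 somite genes 4 rose and none fell; adjusted over the list alone, 6 rose and 1 fell. Camera gave this list an adjusted p of 0.0572, and between 0.0143 and 0.0488 in 9 alternatives. Uncx, of the caudal part of each somite, rose 2.02-fold and Foxc2 1.57-fold. Among 20 second heart field genes 3 rose and 5 fell; adjusted over the list alone, 4 rose and 5 fell. Bmp4 rose from 54.8 ± 4.19 to 90.2 ± 10.4 TPM and Osr1 fell 1.64-fold. No gene of 20 cardiomyocyte markers was called, over all genes or adjusted over the list alone. Their mean log2 level ranged from 2.80 to 5.80 in trex and from 2.70 to 5.52 in wt. Nkx2-5 stood at 15.1 ± 9.93 TPM in trex and 18.2 ± 7.17 in wt, and Tbx5 at 19.0 ± 8.42 and 15.6 ± 4.26 TPM. Among 18 genes of foregut and pharyngeal endoderm 3 rose and 2 fell; adjusted over the list alone, 4 rose and 2 fell. Ripply3, of the caudal pharynx, fell from 37.5 ± 1.87 to 12.98 ± 2.28 TPM and Nkx2-1, of the thyroid and lung primordia, from 4.39 ± 1.23 to 0.486 ± 0.277 TPM, while Nkx2-3 rose 3.35-fold. Leaving out single libraries ended the calls of Foxc2 (5 of 8 libraries, adjusted p up to 0.0989), Uncx (4 libraries, up to 0.0844) and Osr1 (3 libraries, up to 0.076).

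Genes of the low oxygen response and glycolysis were higher in trex, with large differences between the mutant libraries. Of 21 members 14 rose and none fell; adjusted over the list alone, 20 rose. Ddit4, a stress-induced inhibitor of growth signalling, rose from 94.7 ± 7.47 to 869.9 ± 532.5 TPM, with 1336 TPM in trex replicate 1 and 165 in trex replicate 2. Ldha, lactate dehydrogenase, rose from 1718 ± 83.8 to 2988 ± 602 TPM (adjusted p = 0.0142). Mitochondrial transcripts made up 2.61%, 7.15%, 4.82% and 4.50% of TPM in the trex libraries and between 6.73% and 7.95% in wt. Of 24 genes of extracellular matrix and integrins 11 rose and none fell; adjusted over the list alone, 18 rose. Fn1, fibronectin, rose 1.75-fold, Fbn2 1.29-fold and Itga5 1.28-fold. Camera gave adjusted p values of 2.22e-10 for low oxygen genes and 1.53e-07 for matrix genes. With an estimated correlation the adjusted p was 0.585 and 0.29. Leaving out single libraries ended the calls of Ddit4 (6 of 8 libraries, adjusted p up to 0.081), Itga5 (5 libraries, up to 0.0804) and Fn1 (3 libraries, up to 0.0754), and leaving out wt replicate 2 those of Ldha (0.0589) and Fbn2 (0.0519).

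**Figure D3:**
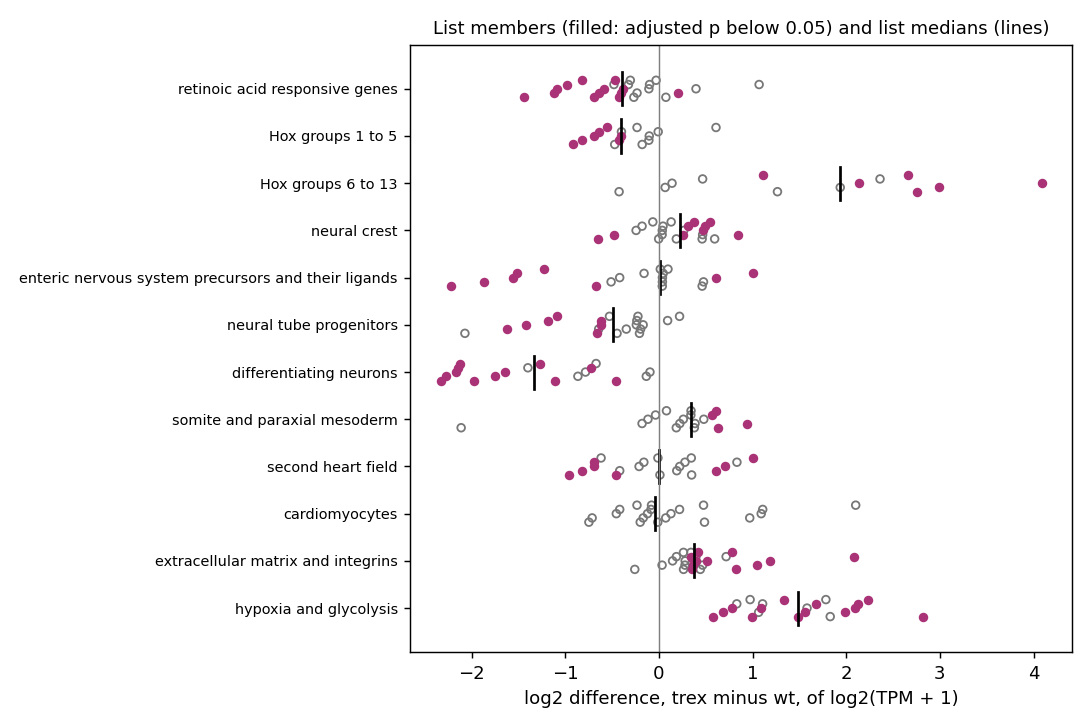
Log2 difference (trex minus wt) of each tested member of 12 gene lists; filled points were called at an adjusted p below 0.05 and the vertical lines are list medians. The medians are -1.33 for differentiating neurons, 1.94 for Hox groups 6 to 13 and 1.49 for hypoxia and glycolysis.

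Over the 40 lists camera called 12 with the preset correlation, 7 higher and 5 lower in trex, and fry called 11. With an estimated correlation none passed. In 18 of the 35 ways to divide the 8 libraries into 4 and 4, the real way included, camera called at least 12 lists. No division other than the real one called more than 18 genes.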

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

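In groups of 4 libraries, 10 of 232 sets of values had a highest or lowest library set far apart from the others by Dixon's criterion, and chance gives about 1 in 20. Of these, 6 were trex replicate 1. It held 106 TPM of Rdh10 where the other trex libraries held 62.7 to 69.0, and 25.2 TPM of Fgf3 where they held 9.97 to 10.3. Its mean log2 level was 4.87 for the FGF pathway (others 4.08 to 4.12), 5.32 for retinoid receptors and co-regulators (5.08 to 5.11), 3.91 for primitive erythroid cells (5.11 to 5.28) and 1.31 for macrophages and platelets (1.88 to 1.92). In wt, replicate 3 held 12.9 TPM of Uncx (others 7.99 to 8.80) and a mean log2 level of 5.29 for BMP and TGF-beta targets (5.37 to 5.38). In wt replicate 1, Foxj1 stood at 7.998 TPM (others 5.58 to 5.98) and the mean log2 level of cell cycle G2/M genes at 7.80 (7.77).

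The tests of trex replicate 1, handling, a more caudal dissection, neural tissue share and embryonic stage below were chosen after their results had been seen at least in part. For the others the expected outcome was written before the result was seen, although the liver covariate and the 6 libraries low in Y-linked transcripts were themselves added after seeing the data. The condition that the libraries of both genotypes not overlap was added to the list tests after their first run and changed no outcome.

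The difference in gene calls was tested against other divisions of the libraries. Of the 35 divisions into 4 and 4, only the real one gave as many as 1369 genes, and the others gave at most 18. A share of 1 in 35 is the smallest possible, and the other divisions mix the genotypes. The count therefore shows that the libraries divide by group, not what sets the groups apart. For the lists, 18 of the 35 divisions gave as many as the real 12 and the highest other gave 18, so chance division is not excluded for the number of lists that camera calls with a preset correlation.

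The rise of low oxygen and glycolysis genes was graded across the mutants. It did not rest on trex replicate 1 alone: without it the list median was 1.11 on the log2 scale, 14 of 21 members were called, and the lowest mutant library (mean log2 level 6.04) still lay above the highest wt library (5.67). A smaller mitochondrial, globin and sex chromosome share did not account for it either, since recomputing TPM without those genes left a median of 1.45. Longer handling of the mutant samples stays open, because immediate early genes gave a camera adjusted p of 0.115, and of 0.741 with an estimated correlation. In 5 alternatives it lay between 0.00749 (without trex replicate 2) and 0.0468. An effect of genotype stays open too, as untested.

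The rise of Hox genes of groups 6 to 13 was weighed against the dissection. With the liver list as a covariate the median was 1.65 and the libraries of the 2 genotypes still did not overlap. That fit takes 1 slope for both genotypes, but the Hox level rose with the liver level in wt and varied little in trex. The size of 1.65 is therefore uncertain. Trex replicates 1 and 2 had lower liver levels (1.20 and 1.85) than wt replicates 3 and 4 (3.33 each). Their Hox levels were higher (3.92 and 4.38 against 3.46 and 3.24), so in these libraries the Hox level did not follow the liver marker level. The liver list also holds yolk sac markers, and liver genes may themselves depend on genotype, which was not tested. Marker levels therefore cannot show how much liver-level tissue a library held, and such tissue stays open as a cause. A mutant dissection that reached further caudally cannot be told apart from an effect of genotype: limb bud and intermediate mesoderm lists gave camera adjusted p values of 0.931 and 0.92, but both tissues may themselves depend on retinoic acid.

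The fall of neuron and neural tube genes was weighed against tissue share, stage and sex. Neurons fell further than progenitors, by 0.719 on the log2 scale (difference -0.719, exact permutation p = 0.0286, the smallest possible). A plain loss of neural tissue predicts an equal fall only if the genes of both lists are expressed nowhere else in the samples. That was not tested, so such a loss stays open. Males among wt did not account for the fall of neuron genes. In the 6 libraries low in Y-linked transcripts the median of the neuron list was -1.35, with all 18 members lower, although no member was called with 2 wt libraries. An earlier stage of the mutants stays open, since early stage genes were higher (camera adjusted p = 0.00432, and 0.29 with an estimated correlation) while the ratio of Hbb-bh1 to Hbb-y, which falls as embryos age, gave an exact permutation p of 0.6. An effect of genotype stays open, as untested.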

How the results depend on the processing

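The alternatives by voom, sex, the 6 libraries low in Y-linked transcripts, pairs of wt libraries, the liver list and camera without a variance trend were chosen after seeing the data; the others were fixed before. No gene called in the reported test was called in the other direction under any of the 24 alternatives run on all genes. The 1369 calls stayed within 1.5 times under the other pseudocounts, the filter at 5, the 3 rescalings, eBayes without trend or robust, voom (1426) and the liver covariate (1051), and 1356 were left when genes near Rdh10 were removed. Without a filter 694 genes were called (344 higher, 350 lower), and with array weights 5524 (3362 and 2162). With a replicate block 687 were called (404 and 283). Same-numbered libraries deviated together with correlations of 0.162, -0.023, -0.004 and 0.252, and 4 of 8 libraries correlated best with their own number. The second principal component fell in the order of the numbers in both groups (25.1 to -29.2 in trex, 22.7 to -12.3 in wt). The labels do not say what a number marks, and numbers 2 and 3 did not deviate together, so the numbers were not used as pairs. Leaving out 1 library gave 199 to 2926 genes (83 to 1710 higher, 116 to 1216 lower), lowest without wt replicate 2 and highest without trex replicate 2. With sex as a covariate 39 were called (9 and 30), and in the 6 libraries low in Y-linked transcripts 8 (2 and 6). Leaving out other pairs of wt libraries gave 9 to 164 calls, so most of such a loss also follows from 2 fewer wt libraries, though the Y-linked pair gave the fewest; 1350 of 1350 compared calls kept their sign without the Y-linked pair, with a median ratio of log2 differences of 0.987. Genes called with a difference of at least 1 on the log2 scale numbered 282 in the reported test. Counted anew, they numbered 121 with a pseudocount of 5, 182 without a filter, 170 at a mean TPM of 5 and 426 with array weights. There were 33 with sex, 8 in the 6 libraries, and 95 to 448 without 1 library. Rescaling shifted the median of all genes by -0.0487 at most.

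Rdh10 stayed higher in all alternatives that hold it; its difference was 0.90 with sex as a covariate (adjusted p = 0.114) and 0.90 in the 6 libraries (adjusted p = 0.207), and 0.75 to 1.00 without 1 library, with the call lost without wt replicate 2. Leaving out genes near Rdh10 removes Rdh10 itself. Of 65 named genes past the threshold none turned its sign, and 4 (Hoxc8, Hk3, Unc5a and Tshz1) kept their call in every alternative that held them. 30 kept it whichever single library was left out; 55 lost it with sex as a covariate, 61 in the 6 libraries, 13 with the replicate block, 13 without a filter, and at most 7 in each other alternative that kept all libraries. The count of lists was 0 with an estimated correlation and 11 to 16 in the other alternatives; beyond that, neural crest lost its call with array weights, the block and without trex replicate 2, mitochondrial genes with quantile normalization and fry, and surface ectoderm with fry. Of the 28 lists not called, 10 passed in some alternative: somites in 9 (adjusted p from 0.0143), proepicardium in 7 (from 0.0108), Wnt targets in 6, fry among them (from 0.0197), BMP and TGF-beta targets in 5 (from 0.0166), immediate early genes in 5 (from 0.00749), primitive erythroid cells in 4 (from 0.0152), the enteric list in 3 (from 0.0188), and cardiomyocytes (array weights, 0.0223), liver (replicate block, 0.0444) and cell cycle (without trex replicate 2, 0.0423) in 1 each.

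The signs that turned belong to results past no threshold, and the cause was not tested. With array weights the log2 difference was -0.42 for Ret and 0.28 for Nkx2-5, and the mean of members minus that of other genes was 0.17 for lung and gut mesenchyme, -0.012 for the FGF pathway and -0.0080 for p53 targets. With the liver covariate it was -0.029 for Tbx5, -0.43 for cardiomyocytes and -0.13 for liver. With sex it was 0.0096 for lung and gut mesenchyme, 0.067 for intermediate mesoderm, 0.039 for Hedgehog and 0.040 for sex chromosome genes, and in the 6 libraries 0.0052, 0.063 and 0.035 for the first 3 of these. At a mean TPM of 5 it was 0.15 for intermediate mesoderm, 0.13 for notochord and 0.034 for Hedgehog, which had 0.018 with a pseudocount of 5 and 0.0071 with quantile normalization. Without 1 library the values ran from -0.29 to 0.29 for Ret, -0.020 to 0.47 for Tbx5, -0.079 to 0.12 for hindbrain segmentation, -0.39 to 0.60 for cardiomyocytes, -0.043 to 1.10 for liver, -0.22 to 0.15 for lung and gut mesenchyme, -0.13 to 0.074 for intermediate mesoderm and -0.037 to 0.023 for Hedgehog. Depth limits Mir7059, with at most 2 reads in any library, and mt-Tl1, with 3 to 39 reads in trex and 49 to 69 in wt.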

Other observations

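Further lists were fixed before the data were examined. Of 18 endothelial genes 4 rose, among them Etv2, 1.69-fold (camera adjusted p = 0.000579, and 0.585 with an estimated correlation), and of 12 surface ectoderm genes 3 rose, among them Krt8, 2.22-fold (camera adjusted p = 0.00186, 0.585 with an estimated correlation, and 0.0588 with fry). Of 8 early embryonic stage genes 3 rose, with Hmga2 1.28-fold higher (camera adjusted p = 0.00432, and 0.29 with an estimated correlation). Mitochondrially encoded genes passed camera as lower (adjusted p = 0.00186, and 0.585 with an estimated correlation) without a called member among 6; adjusted over the list alone, 6 fell. The adjusted p of this list was 0.136 with fry and 0.0691 with quantile normalization, where the mean of its members minus that of other genes was -0.483 on the log2 scale against -0.765 in the reported test. In the pharyngeal arch list 4 of 17 genes rose and 2 fell, with Dlx5 2.30-fold higher, and in the lung and gut mesenchyme list 2 of 14 rose and 2 fell. In the BMP and TGF-beta list 4 of 13 rose and 1 fell, with Tgfbi 1.64-fold higher. Adjusted over the list alone, 7 endothelial, 5 surface ectoderm and 6 early stage genes rose, as did 7 pharyngeal arch genes (4 fell), 3 of lung and gut mesenchyme (3 fell) and 6 of the BMP and TGF-beta list (3 fell). Leaving out wt replicate 2 ended the calls of Etv2 (adjusted p = 0.0523) and Dlx5 (0.054), leaving out it or trex replicate 4 that of Hmga2 (up to 0.0703), and leaving out any of 5 libraries that of Krt8 (up to 0.087).

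Camera called none of the other lists in the reported test. Those with called genes were limb bud (1 of 14 higher, 1 lower), otic and placodal genes (1 of 13 higher, 3 lower), forebrain and midbrain (2 of 7 lower, En1 3.79-fold), tail bud (1 of 9 higher, 2 lower, Lfng 1.68-fold), intermediate mesoderm (1 of 10 lower), proepicardium (2 of 9 higher, Krt19 5.12-fold), notochord and floor plate (1 of 10 lower), FGF pathway (2 of 17 higher), Hedgehog pathway (2 of 13 higher, Gli2 1.23-fold), canonical Wnt targets (2 of 13 higher, Lef1 1.498-fold), p53 targets (3 of 17 higher, 2 lower, Trp53inp1 1.45-fold lower) and immediate early genes (2 of 12 higher, 1 lower, Ier3 13.5-fold). No gene was called among 14 of liver and yolk sac, 18 of primitive erythroid cells, 6 of macrophages and platelets, 18 of the cell cycle or 5 sex chromosome genes, nor adjusted over the list alone. In the lists before these, the genes higher and lower adjusted over the list alone were 1 and 1 for limb bud, 2 and 3 for otic and placodal genes, 1 and 2 for forebrain and midbrain, 3 and 4 for tail bud, 2 and 2 for intermediate mesoderm, 3 and 0 for proepicardium, 1 and 1 for notochord and floor plate, 2 and 1 for the FGF pathway, 2 and 0 for Hedgehog, 2 and 0 for Wnt targets, 4 and 4 for p53 targets and 4 and 1 for immediate early genes. Of the genes named there, Ier3 and Krt19 lost their call without 7 and 6 of the 8 libraries, Gli2 without 5, Lfng without 4, Trp53inp1 without 3, En1 without 2 and Lef1 without 1. For 10 of the 28 lists that camera did not call, the median, the mean and the test differed in sign.

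Around Rdh10 on chromosome 1, 11 of 87 tested genes within 20 Mb were called, 12.6% against 8.69% elsewhere (Fisher's exact test, two-sided, p = 0.182). Both counts and the test include Rdh10 itself, which was called.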
